A study of Drosophila melanogaster with 12 samples.

How the data were processed

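Total RNA from larval eye discs of Drosophila melanogaster was hybridised to Affymetrix expression arrays, with 4 genotypes and 3 biological replicates of each, 12 arrays in all. Per the labels, flies were kept at 25 degrees Celsius and biotin-labelled cRNA was made from 100 ng of total RNA. The deposited values are log2 expression per probe set, on a scale from which background, normalization and summary methods cannot be read. The R package affy is the only tool named, per the submitters' processing notes, and its version and settings are not given in the sources used here. The value table held 18952 probe sets, of which 183 Affymetrix control probe sets were left out, so 18769 were tested. Array means lay between 5.96 and 6.02 and array medians between 4.71 and 4.90 on the log2 scale, and upper quartiles between 7.71 and 8.28. The scale was not changed, and quantile normalization was run as an alternative. The number of arrays limits the precision.

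The authors' deposited table is a separate source. It lists 13281 genes by FlyBase identifier and symbol and gives, for each of the 3 transgenic genotypes over the control, the average log2 fold change, a p-value for higher and another for lower expression, and the estimated proportion of false positives up to that gene (pfp), per the file headers. These are rank product results of the authors, whose settings are not given in the sources used here. The table has no value per array, so its numbers carry no SD or n here. A gene was called at a pfp under 0.05 in the direction of its fold change. Of the genes with an absolute log2 change of at least 1, 301 in number, 100% had a probe set within 0.01 in all 3 fold changes, against 0% after the comparisons were shuffled, so both sources hold the same arrays. Probe sets carry no gene names in the files and were not named from their values, so they are given by identifier, at most 2 in each direction per comparison. Symbols are those of the table, and 12786 of its genes matched a symbol or a unique synonym in a RefSeq gene table of the Release 6 assembly, used only for current names and for the order of genes.

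Each of 8 comparisons was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) over all 12 arrays with genotype as the only term, and probe sets were called at a Benjamini-Hochberg adjusted p under 0.05. The comparisons were the 3 transgenic genotypes against the control, both transgenes against each alone, the mean miR-11 effect, the mean dE2F1/dDP effect and their interaction. The test was checked on simulated data with 50 changed probe sets of each size among 18769. For miR-11 against the control it recovered 78% of the changes of log2 size 1 and 86% of those of size 2, and for the interaction 34% and 84%. These shares are likely too high for the arrays. The simulated data gave 191 and 161 calls, against 29 and 9 on the arrays, and a longer list of calls eases the adjusted cutoff. The simulated noise was also independent between probe sets.

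Gene lists were written before the data were examined, and so were the tests, the alternatives and the rule for named genes. There were 24 lists, including ribosomal proteins by name pattern. Because probe sets have no names, lists were tested on the log2 fold changes of the authors' deposited table with limma's cameraPR at a preset correlation of 0.01, Benjamini-Hochberg adjusted over the 24 lists within each comparison. This replaces the planned test on arrays. It compares a list with all other genes, uses genes and not arrays as its units, and cannot be repeated with an estimated correlation or without an array. Where the genes of a list vary together beyond the preset correlation, its p-values are too small. They do not measure replication over animals. A preset correlation of 0.05, a test on ranks and the E2F pathway list without E2f and Dp were added after seeing the data. Counts adjusted over the list alone use the table's p-values, the smaller of the 2 doubled.

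The rule for named genes was to give E2f, Dp, w, rpr, W, grim and skl always, the 6 largest rises and 6 largest falls among called genes, and, from each list past its test plus 4 lists always described, up to 4 called members or otherwise the member with the smallest p. With no values per array for named genes, pfp took the place of the adjusted p and the condition that groups do not overlap was dropped. Comparisons that the table lacks were formed as differences of its log2 fold changes and have no test per gene. There the largest differences among genes called in at least 1 comparison of the table are named, and the list member with the largest absolute difference. These changes to the rule were made after seeing the files. For 1 list in 1 of these comparisons the member is not reported here.

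Replicate numbers are shared between genotypes in the labels. Of the 18 same-number pairs of arrays, 6 correlated above 0.1 in their deviations from the group means, so the numbers were not taken to pair the arrays. A batch by replicate number is not excluded by this, and a block for the number was run as an alternative. No 2 arrays held the same values (Pearson r between 0.927 and 0.995). A test of miR-11 seed sites in messenger RNA was planned and not run, because no genome was used here. Further tools were Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.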

Results

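Gene expression was profiled in eye discs, the larval epithelium from which the adult eye forms, of Drosophila larvae. All animals carried GMR-Gal4, a driver that acts behind the morphogenetic furrow, the front at which disc cells begin to differentiate. The 4 genotypes, with 3 biological replicates each, were the driver control, the driver with the microRNA miR-11, the driver with dE2F1 and dDP, and the driver with all 3 transgenes. dE2F1 and dDP form a transcription factor that activates genes of the cell cycle. The design asks what each transgene does to the transcriptome and whether miR-11 changes the response to dE2F1/dDP.

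Arrays of the same genotype differed widely. The first principal component held 63.1% of the variance, and 22.7% of its spread lay between genotypes (permutation p = 0.54). Its mean score was 12.9 ± 32.2 (SD, n = 3) in the control, 23.3 ± 58.7 with miR-11, -20.1 ± 47.3 with dE2F1/dDP and -16.1 ± 16.2 with both. The component rose with the mean signal of the bacterial hybridization spike-ins over the 12 arrays (Pearson r = 0.77, permutation p = 0.00354, adjusted p = 0.00885 over 5 relations; Spearman rho = 0.66, permutation p = 0.0242, adjusted p = 0.0403). Without the 2 arrays farthest from the median spike-in signal, r was 0.53 (permutation p = 0.113), so the relation rests in part on those. Spike-in signal itself was 10.51 ± 0.45 (log2, SD, n = 3) in the control, 10.94 ± 0.53 with miR-11, 10.48 ± 0.58 with dE2F1/dDP and 10.69 ± 0.31 with both.

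**Figure D1:**
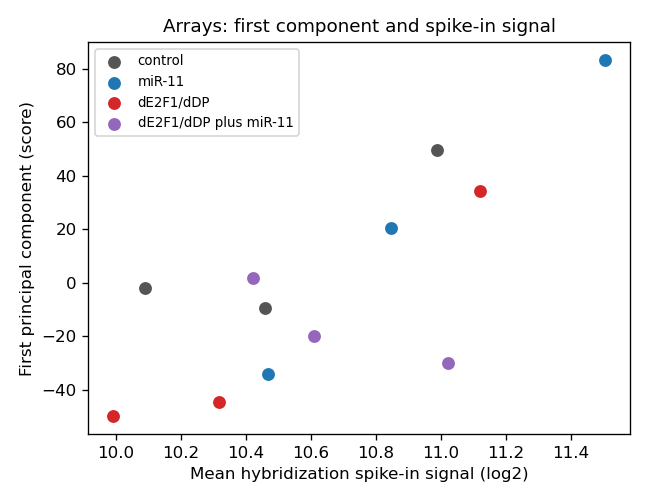
Score of each array on the first principal component of all probe sets (vertical axis) against its mean hybridization spike-in signal in log2 (horizontal axis), 1 point per array, coloured by genotype. The 3 miR-11 arrays run from -34.0 to 83.3 on the component, over almost the whole range of the 12 arrays.

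The transgenes were looked at first. Dp, the gene of dDP, rose 7.23-fold with dE2F1/dDP (log2 2.85) and 6.63-fold with all 3 transgenes (log2 2.73) in the authors' deposited table, and stood at log2 -0.29 with miR-11 alone. The white gene w, whose mini copy usually marks such transgenes, rose 5.10-fold and 5.97-fold in the same genotypes and was at log2 1.19 with miR-11 alone (pfp = 0.0765, not called) in the authors' deposited table. E2f, the gene of dE2F1, was at log2 0.34 with dE2F1/dDP and 0.33 with both in the authors' deposited table, and was not called in either. A probe set outside the transgene's cDNA would not report it, and no array value can be tied to E2f here. Mature miR-11 was not measured.

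miR-11 was compared with the control to show its effect alone. CG9150 rose 18.4-fold and CG18278 rose 11.9-fold (log2 3.58) in the authors' deposited table. TotA, a secreted stress-response peptide, rose 12.1-fold (log2 3.60), CG14957 16.6-fold, CG14332 10.9-fold and CG33333 9.38-fold in the authors' deposited table. Among the falls in the authors' deposited table were Gyc-89Da, a guanylyl cyclase (log2 -3.63), CG2177, a zinc transporter gene now called Zip102B (log2 -3.37), krimp, a component of the germline piRNA machinery (log2 -2.38), the cytochrome P450 Cyp4g1 (log2 -1.96), Hsp70Ba (log2 -1.93) and Rbm13 (log2 -1.73). In all, 41 of 13281 genes were called higher and 19 lower in the authors' deposited table.

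Genes of tissues next to the disc also moved with miR-11. The salivary gland list was higher (15 of 20 genes positive, median log2 0.25, adjusted p = 1.83e-26, and 0.00546 on ranks), with the glue protein genes Sgs4 (4.70-fold) and Sgs3 (4.01-fold) called in the authors' deposited table. The fat body list was higher as well (12 of 16 positive, median log2 0.45, adjusted p = 3.85e-12, and 0.0373 on ranks). Its storage protein gene Lsp1gamma (log2 1.87) and Obp99b (log2 1.98) rose and Obp44a (log2 -1.42) fell in the authors' deposited table. Adjusted over the list alone, 10 salivary genes were higher and 0 lower, and 8 fat body genes were higher and 1 lower. The hemocyte list had a median of 0.10 (adjusted p = 0.0103), and nimC1, a phagocytosis receptor of blood cells, rose (log2 1.54) in the authors' deposited table. It had 2 members higher adjusted over the list alone, and its call was lost with the correlation preset at 0.05 (adjusted p = 0.0969).

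Cell cycle lists sat slightly lower with miR-11, with 0 members called in the authors' deposited table. Of 48 DNA replication and S phase genes 44 were negative (median log2 -0.14, adjusted p = 0.0103), and of 52 G2 and mitosis genes 44 were negative (median log2 -0.26, adjusted p = 0.00334). The smallest p in each belonged to CG15220, which encodes RPA3 (log2 -0.32), and the condensin gene glu (log2 -0.51) in the authors' deposited table. Lists for DNA damage and repair (median log2 -0.16, adjusted p = 0.0397), glia (median log2 -0.15, adjusted p = 0.0101) and heat shock and stress (median log2 -0.17, adjusted p = 0.0103) were also lower, although TotA of the last list rose. Their members with the smallest p in the authors' deposited table included mus308 (log2 -0.44) and Mdr65 (log2 -1.15), and neither was called. All 5 of these calls were lost with the correlation preset at 0.05 (adjusted p = 0.168, 0.0977, 0.196, 0.0969 and 0.0977 in the order given). When adjusted over the list alone, 0 replication, mitosis or repair genes were called, against 3 lower glia genes and 1 higher and 4 lower stress genes.

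Cell death genes and the Notch-regulated genes of the E(spl) complex and Bearded family list did not pass with miR-11. Pairing sites for miR-11 were not looked for in the genes of either list. In the cell death list 8 of 24 genes were positive (median log2 -0.03, adjusted p = 0.985). The proapoptotic genes rpr (log2 -0.17), W, known as hid (log2 0.07), grim (log2 -0.05) and skl (log2 -0.42) were not called in the authors' deposited table, nor was the apoptosis inhibitor Bruce (log2 -0.27). In the E(spl) complex and Bearded family list 14 of 19 genes were negative (median log2 -0.10, adjusted p = 0.319), and HLHm5 had the smallest p (log2 -0.52, not called) in the authors' deposited table. E2f was at log2 0.04 in the authors' deposited table. No gene of either list was called when adjusted over the list alone.

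On the arrays, limma called 18 probe sets higher and 11 lower with miR-11. Probe set 1641174_at went from 4.06 ± 0.18 (SD, n = 3) to 9.41 ± 0.79 (log2 change 5.35, SE 0.39, adjusted p = 0.000214), and 1629242_x_at from 10.41 ± 0.31 to 6.10 ± 0.36 (log2 change -4.31, SE 0.29, adjusted p = 0.000103). The total of 29 became 16 without miR-11 replicate 2, 14 without control replicate 3 and 45 without miR-11 replicate 1. A fit on the 6 arrays of these groups alone called 10.

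dE2F1/dDP was compared with the control to show the response to the transcription factor. Besides Dp and w, the cytochrome P450 gene Cyp6a17 rose by log2 4.09, CG14545 4.56-fold, Sgs4 3.75-fold and the sugar transporter gene sut2 3.70-fold in the authors' deposited table. Falls in the authors' deposited table were led by Gyc-89Da (log2 -3.65), CG2177 (log2 -3.34), CG9021 (log2 -2.92), CG13840 (log2 -2.78), Cyp4g1 (log2 -2.50) and CG4250 (log2 -2.23). There were 18 genes called higher and 28 lower in the authors' deposited table.

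Genes of the cell cycle stood higher as groups with dE2F1/dDP. The spread of the arrays ran with this comparison, the first component averaging -20.1 with dE2F1/dDP and 12.9 in the control, for these lists and for those of disc identity below. Of the 48 replication and S phase genes 39 were positive (median log2 0.29, adjusted p = 1.16e-06). Mcm10, a replication initiation factor, had the smallest p in the authors' deposited table (log2 1.21, pfp = 0.143). Of the 52 G2 and mitosis genes 41 were positive (median log2 0.25, adjusted p = 0.000146), although the member with the smallest p, Cks85A, was negative (log2 -0.75) in the authors' deposited table. E2F pathway components had 14 of 16 positive (median log2 0.36, adjusted p = 1.16e-06), with only Dp called over all genes in the authors' deposited table, itself a transgene. Without E2f and Dp, the genes of the transgenes, that list kept its call (median log2 0.35, adjusted p = 0.00299). DNA damage and repair genes had a median of 0.22 (adjusted p = 0.00203), with RecQ5, a DNA helicase, at log2 0.96 in the authors' deposited table. Hippo and growth genes had a median of 0.25 (adjusted p = 0.000278), with the S phase regulator CycE at log2 0.99 (pfp = 0.281) in the authors' deposited table. Among these lists, adjusted over the list alone, 1 replication gene, 2 E2F pathway genes and 0 mitosis, repair or growth genes were called, all higher.

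Genes of disc identity were higher as groups with dE2F1/dDP too. All 24 eye progenitor and retinal determination genes were positive (median log2 0.44, adjusted p = 1.26e-07), with the signalling ligand gene dpp at log2 0.76 in the authors' deposited table. Antennal disc genes had 13 of 14 positive (median log2 0.50, adjusted p = 0.000146), with the antennal selector ss at log2 0.67 in the authors' deposited table. Photoreceptor and retinal neuron genes had 27 of 35 positive (median log2 0.36, adjusted p = 1.43e-05), while the receptor gene sev was at log2 -0.69 in the authors' deposited table. JNK and wound response genes had a median of 0.38 (adjusted p = 0.000177; scarface at log2 1.01 in the authors' deposited table), and ecdysone response genes 0.22 (adjusted p = 0.00301; br at log2 1.04 in the same table). Cone and pigment cell genes had a median of 0.39 (adjusted p = 0.0485; the homeobox gene ct at log2 0.89 in the authors' deposited table), a call lost with the correlation preset at 0.05 (adjusted p = 0.094). Of these 6 lists, only the ecdysone list had members called when adjusted over the list alone, 2 higher.

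Fat body genes were lower with dE2F1/dDP (11 of 16 negative, median log2 -0.24, adjusted p = 0.00509, but 0.0772 on ranks), and Obp44a fell (log2 -1.68) in the authors' deposited table. The salivary list passed as higher on its mean (0.24, adjusted p = 0.00509) while its median was negative at -0.05 and its test on ranks did not pass (adjusted p = 0.669). Sgs4 (log2 1.91), Sgs3 (log2 1.77) and Eig71Ee (log2 1.65) of that list rose in the authors' deposited table. Adjusted over the list alone, 7 salivary genes were higher and 2 lower, and 2 fat body genes were lower. The cell death list had 14 of 24 positive (median log2 0.07, adjusted p = 0.249), and the E(spl) complex and Bearded list 8 of 19 (median log2 -0.10, mean 0.003, adjusted p = 0.907). Neither had a member called over all genes or adjusted over the list alone. In the authors' deposited table W stood at log2 0.33, rpr at 0.07, grim at -0.05 and skl at -0.33, and the smallest p belonged to CG17836, which encodes Xrp1 (log2 0.94), and to the corepressor gene gro (log2 0.78).

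limma called 6 probe sets higher and 6 lower with dE2F1/dDP. Probe set 1628052_at rose from 3.77 ± 0.26 (SD, n = 3) to 7.86 ± 0.24 (log2 change 4.09, SE 0.18, adjusted p = 5.99e-06; the start lies at the level of the arrays' lower quartiles, 3.75 to 3.97, so the change is a lower bound), and 1624543_s_at fell from 8.65 ± 0.43 to 4.90 ± 0.21 (log2 change -3.75, SE 0.24, adjusted p = 0.000108). With miR-11 alone 1624543_s_at fell as far (log2 change -3.89, adjusted p = 9.96e-05). Of the 12 calls, 7 were called the same way in all 3 transgenic genotypes, 5 of them falls, and so are not particular to dE2F1/dDP. Those 7 are also among the 29 probe sets called with miR-11 and the 17 with all 3 transgenes. The total of 12 ranged from 5 without dE2F1/dDP replicate 1 to 19 without miR-11 replicate 3. The list values above could not be recomputed without single arrays.

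All 3 transgenes together were compared with the control. CG18278 (log2 3.97) and CG9150 (log2 3.46) rose as with miR-11 alone, Dp and w rose as with dE2F1/dDP, and CG13705 (5.33-fold) and the cuticle protein gene Cpr100A (3.51-fold) rose in the authors' deposited table. Falls in the authors' deposited table were led by Gyc-89Da (log2 -3.58), CG2177 (log2 -3.39), CG13840 (log2 -2.88), CG9021 (log2 -2.60), krimp (log2 -2.09) and Akh, the adipokinetic hormone gene (log2 -2.08). There were 31 genes called higher and 82 lower in the authors' deposited table.

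Muscle genes were higher with all 3 transgenes, with 19 of 21 positive (median log2 0.67, adjusted p = 1.1e-13). Prm, paramyosin (log2 1.36), and Mhc, muscle myosin heavy chain (log2 1.33), were called in the authors' deposited table, and 13 muscle genes were higher when adjusted over the list alone. Salivary gland genes were lower (18 of 20 negative, median log2 -0.79, adjusted p = 1.98e-23, and 2.67e-06 on ranks). In the authors' deposited table Sgs7 (log2 -1.75), Sgs8 (log2 -1.82), ng1 (log2 -1.84) and ng3 (log2 -1.93) fell, and 8 genes were lower when adjusted over the list alone.

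Cell cycle and eye lists were higher with all 3 transgenes. The spread of the arrays ran with this comparison too, the first component averaging -16.1 with all 3 transgenes and 12.9 in the control. Replication and S phase genes had a median of 0.32 (39 of 48 positive, adjusted p = 7.34e-08; Mcm10 at log2 1.06, pfp = 0.0622 in the authors' deposited table). G2 and mitosis genes had a median of 0.20 (41 of 52 positive, adjusted p = 0.000372; the kinetochore gene Nuf2 at log2 0.78 in the authors' deposited table). E2F pathway components had a median of 0.35 (adjusted p = 1.81e-07, and 0.00132 without E2f and Dp), and Hippo and growth genes 0.27 (adjusted p = 0.00251; CycE at log2 1.04, pfp = 0.0668 in the authors' deposited table). Eye progenitor and retinal determination genes had a median of 0.31 (23 of 24 positive, adjusted p = 1.92e-05; dpp at log2 0.73 in the authors' deposited table). Photoreceptor genes had a median of 0.29 (adjusted p = 0.000122; sev at log2 -0.62 in the same table) and antennal genes 0.17 (adjusted p = 0.00528; ss at log2 0.82 in the authors' deposited table). Adjusted over the list alone, 2 replication genes, 2 E2F pathway genes and 2 growth genes were higher, and 0 mitosis, eye, photoreceptor or antennal genes were called.

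Another 7 lists passed with all 3 transgenes at the preset correlation of 0.01 and not at 0.05. The hemocyte gene nimC1 rose in the authors' deposited table (log2 1.31; list median 0.29, adjusted p = 0.00851 and 0.0529 at the 2 settings). Hsp70Ba (log2 -1.72) and Hsp70Aa (log2 -1.25) of the stress list fell in the authors' deposited table (list median -0.12, adjusted p = 0.0164 and 0.0789), and so did Obp44a (log2 -1.47) of the fat body list (list median -0.22, adjusted p = 0.02 and 0.0789). ImpL3, lactate dehydrogenase, stood at log2 1.14 (pfp = 0.0617) in the authors' deposited table and belongs to both the ecdysone list (adjusted p = 0.0409 and 0.153) and the JNK list (adjusted p = 0.00707 and 0.0514). The repair list (adjusted p = 0.007 and 0.0718; RecQ5 at log2 0.97 in the authors' deposited table) and the glia list (adjusted p = 0.02 and 0.0789; CG30035, a trehalose transporter gene, at log2 1.10 in the same table) were positive in the median, at 0.09 and 0.19. Adjusted over the list alone, the higher and lower counts were 2 and 0 for hemocyte, 0 and 6 for stress, 1 and 5 for fat body, 1 and 1 for ecdysone, 2 and 0 for JNK, 0 and 0 for repair, and 4 and 1 for glia.

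Cell death genes had a negative median of -0.09 but a mean near 0 and a test on the positive side with all 3 transgenes (11 of 24 positive, adjusted p = 0.962), and in the authors' deposited table W stood at log2 0.05, rpr at 0.03, grim at 0.08 and skl at -0.32, with the smallest p for CG17836 (log2 0.82). The E(spl) complex and Bearded list had a median of -0.06 (adjusted p = 0.993; gro at log2 0.82 in the authors' deposited table). Neither list had a called member, over all genes or adjusted over the list alone. limma called 8 probe sets higher and 9 lower. Probe set 1631549_s_at rose from 4.35 ± 0.31 (SD, n = 3) to 8.32 ± 0.19 (log2 change 3.97, SE 0.33, adjusted p = 0.00073), and 1626088_at fell from 7.69 ± 0.04 to 4.30 ± 0.05 (log2 change -3.39, SE 0.10, adjusted p = 1.35e-07). The total of 17 dropped to 9 without control replicate 3 or without replicate 3 of the genotype itself, and to 10 without its replicate 1.

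**Figure D2:**
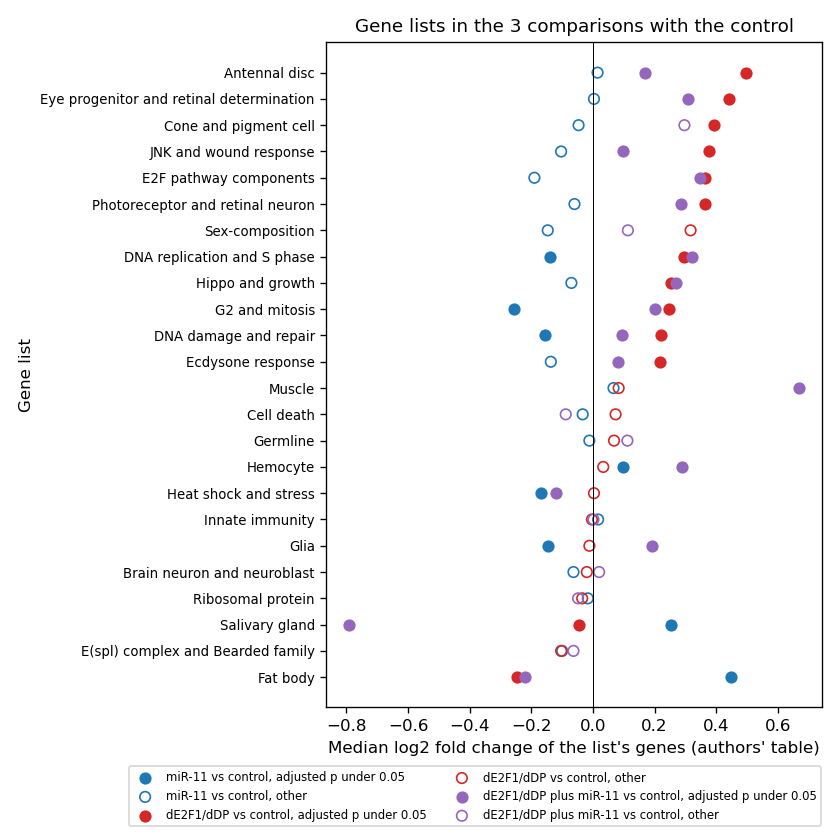
Median log2 fold change of each gene list (horizontal axis, authors' deposited table) for the 24 lists (vertical axis), in each transgenic genotype over the control. Filled circles have an adjusted p under 0.05 with the preset correlation of 0.01 and open circles do not. Salivary gland genes lie at 0.25 with miR-11 and -0.79 with all 3 transgenes, and DNA replication genes at -0.14, 0.29 and 0.32.

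Overlaps between these comparisons involve the same 3 control arrays, which could not be split further. With miR-11 and with all 3 transgenes, 17 genes were called lower in both and 6 higher in both in the authors' deposited table. Top lists of probe sets of these lengths from simulated groups with no effect shared 9.71 (at most 19) and 11.7 (at most 28) on average, and independent lists would share 0.117 and 0.0957. With dE2F1/dDP and with all 3 transgenes, 25 genes were called lower in both (simulated mean 12.4, at most 28; independent lists 0.173) and 9 higher (simulated mean 6.93; independent lists 0.042) in the authors' deposited table. With miR-11 and with dE2F1/dDP, the authors' deposited table had 8 shared lower calls (simulated mean 6.52; independent lists 0.0401) and 4 shared higher calls (simulated mean 7.49; independent lists 0.0556). Part of any excess may come from the shared controls.

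Adding miR-11 to dE2F1/dDP was examined next, as the difference between all 3 transgenes and dE2F1/dDP. CG18278 (log2 3.93) and CG9150 (log2 3.51) stood higher, followed by CG13705 (2.41), Cpr100A (2.07), CG7203 (2.01) and CG14374 (1.97), as differences of the authors' deposited table that carry no test per gene. On the low side of the authors' deposited table were Cyp6a17 (log2 -4.18), Sgs4 (-2.93), Sgs5 (-2.72), Sgs3 (-2.72), Sgs8 (-2.67) and Sgs7 (-2.61). The salivary list was lower (17 of 20 negative, median log2 -0.51, adjusted p = 2.03e-87, and 1.89e-05 on ranks) and the muscle list higher (18 of 21 positive, median log2 0.51, adjusted p = 6.75e-25, and 6.21e-06 on ranks), with Unc-89, the muscle protein obscurin, at log2 1.58 from the authors' deposited table. The stress list was lower (median log2 -0.05, adjusted p = 0.0135; Hsp70Ba at log2 -1.19 from the authors' deposited table), a call lost with the correlation preset at 0.05 (adjusted p = 0.147).

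The 4 lists always described did not pass when miR-11 was added to dE2F1/dDP. Replication genes had a median of 0.03 (adjusted p = 0.868), G2 and mitosis genes 0.01 (mean -0.02, adjusted p = 0.678), cell death genes -0.05 (adjusted p = 0.172) and E(spl) complex and Bearded genes 0.02 (mean -0.01, adjusted p = 0.908). For the mitosis and Bearded lists the median is thus positive while mean and test are negative. The eye progenitor list did not pass either (19 of 24 negative, adjusted p = 0.123), but did on ranks (adjusted p = 0.0231). In the authors' deposited table the largest differences of the last 3 of these lists belonged to Klp10A (log2 -0.32), the TNF ligand gene egr (-0.80) and m4 (-0.20). The proapoptotic genes differed by log2 -0.28 for W, -0.04 for rpr, 0.13 for grim and 0.01 for skl, and E2f by -0.01, Dp by -0.12 and w by 0.23, from the authors' deposited table. limma called 6 probe sets higher and 1 lower. Probe set 1641174_at rose from 3.91 ± 0.31 (SD, n = 3) to 8.77 ± 0.62 (log2 change 4.85, SE 0.39, adjusted p = 0.00121), and 1628052_at fell from 7.86 ± 0.24 to 3.68 ± 0.05 (log2 change -4.18, SE 0.18, adjusted p = 9.65e-06). Both low levels lie at or below the arrays' lower quartiles (3.75 to 3.97), so these changes are lower bounds in size. The total of 7 was 4 without replicate 1 or replicate 3 of the genotype with all 3 transgenes.

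Adding dE2F1/dDP to miR-11 was examined in the same way. Dp (log2 3.02), CG9297 (1.94), the GTPase gene Rala (1.78), the glycogen phosphorylase gene GlyP (1.65), CG14545 (1.54) and CG13705 (2.83-fold) stood higher as differences of the authors' deposited table, and w by 1.39. CG12310 (log2 -4.47), CG14265 (-4.27), TotA (-4.24), CG11300 (-4.05), Pig1 (-4.03) and CG14957 (-3.92) stood lower in the authors' deposited table. These 6 had all been called higher with miR-11 alone. The salivary list was lower (median log2 -1.02, adjusted p = 3.48e-56, and 1.74e-06 on ranks; Sgs8 at log2 -3.56 from the authors' deposited table), as was the fat body list (median log2 -0.65, adjusted p = 1.71e-11; Obp99b at -2.53 from the same table).

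The spread of the arrays ran with this comparison as well, the first component averaging -16.1 with all 3 transgenes and 23.3 with miR-11 alone, for all lists below. Replication genes had 39 of 48 positive (median log2 0.52, adjusted p = 1.39e-10; the ribonucleotide reductase gene RnrL at log2 1.26 from the authors' deposited table), and G2 and mitosis genes 46 of 52 (median log2 0.42, adjusted p = 1.07e-07; glu at 0.99 from the same table). E2F pathway (median 0.59, adjusted p = 1e-08, and 4.27e-05 without E2f and Dp), repair (0.29, 9.47e-05; tos at log2 1.18 from the authors' deposited table) and growth genes (0.29, adjusted p = 0.00115; CycE at log2 1.15) were higher. Eye progenitor (0.35, adjusted p = 0.000417; dpp at log2 0.72 from the authors' deposited table), photoreceptor (0.30, adjusted p = 9.47e-05), glia (0.32, adjusted p = 8.73e-05; pnt, a member of both lists, at log2 1.45) and muscle genes (0.53, adjusted p = 3.85e-07; Prm at log2 1.36) were higher as well. The antennal (adjusted p = 0.0253; ss at log2 1.08), ecdysone (adjusted p = 0.0154; ImpL1 at 1.48), germline (adjusted p = 0.0352; spn-E at 0.997) and JNK lists (adjusted p = 0.0181; ImpL3 at 0.98, all genes from the authors' deposited table) passed as higher. They lost that with the correlation preset at 0.05 (adjusted p = 0.0806, 0.0831, 0.109 and 0.0806). Cell death (median -0.01 but mean 0.04 and a positive test, adjusted p = 0.874; CG17836 at log2 0.85) and E(spl) complex and Bearded genes (0.03, adjusted p = 0.439; gro at 0.75, both genes from the authors' deposited table) did not pass. W differed by -0.02, rpr by 0.20, grim by 0.13, skl by 0.10 and E2f by 0.29 in the authors' deposited table.

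limma called 3 probe sets higher and 7 lower when dE2F1/dDP was added to miR-11. Probe set 1629242_x_at rose from 6.10 ± 0.36 (SD, n = 3) to 10.15 ± 0.24 (log2 change 4.05, SE 0.29, adjusted p = 0.000571). Probe set 1638279_at fell from 9.44 ± 0.72 to 6.40 ± 0.52 (log2 change -3.05, SE 0.37, adjusted p = 0.0353), and was past the threshold neither after quantile normalization nor with a block for the replicate number, nor without most single arrays. The total of 10 was 3 after quantile normalization and ranged from 3 (without miR-11 plus dE2F1/dDP replicate 1, among others) to 48 (without miR-11 replicate 1).

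The mean miR-11 effect averages its change without and with dE2F1/dDP. CG9150 (log2 3.86), CG18278 (3.76), CG14957 (2.05), TotA (1.88), CG33333 (1.83) and the P450 gene Cyp6a13 (1.74) were highest, and Cyp6a17 (-2.10), CG2177 (-1.71), krimp (-1.71), Hsp70Ba (-1.56), CG31918 (-1.40) and CG9822 (-1.39) lowest, in averages from the authors' deposited table. Several of these averages come almost wholly from 1 of the conditions. In the authors' deposited table, Cyp6a17 changed by -4.18 with dE2F1/dDP present. Without it, CG2177 changed by -3.37, TotA by 3.60 and CG14957 by 4.05. CG2177 fell as much (-3.34) with dE2F1/dDP alone. Muscle (median 0.30, adjusted p = 5.03e-12; Unc-89 at log2 0.74), fat body (0.30, adjusted p = 1.54e-08; Obp99b at 0.94) and hemocyte genes (0.09, adjusted p = 0.00126; nimC1 at 1.08, all 3 genes from the authors' deposited table) were higher. The muscle list had not passed without dE2F1/dDP (median 0.07, adjusted p = 0.319) and had a median of 0.51 with it. The fat body list had a median of 0.45 without dE2F1/dDP and did not pass with it (median 0.05, adjusted p = 0.498). Salivary (median -0.14, adjusted p = 0.00132, an average of a rise without dE2F1/dDP, median 0.25, and a fall with it, median -0.51; Sgs7 at log2 -0.67), stress (-0.13, adjusted p = 0.000276, although TotA is a member) and G2 and mitosis genes (-0.12, adjusted p = 0.00899; Klp10A at -0.32) were lower, the genes again from the authors' deposited table. The mitosis call was lost with the correlation preset at 0.05 (adjusted p = 0.184). Replication (41 of 48 negative, median log2 -0.08, adjusted p = 0.115, but 0.0102 on ranks; DNApol-alpha180 at -0.28), cell death (median -0.05; egr at -0.40) and E(spl) complex and Bearded genes (median -0.10; HLHm5 at -0.28, all from the authors' deposited table) did not pass. W stood at -0.10, rpr at -0.11, grim at 0.04, skl at -0.21, E2f at 0.02, Dp at -0.21 and w at 0.71 in the authors' deposited table. limma called 11 probe sets higher and 11 lower, among them 1623971_at (log2 change 3.86, SE 0.20, adjusted p = 2.35e-05) and 1628052_at (-2.10, SE 0.13, adjusted p = 5.59e-05), over 6 arrays against 6. For 1628052_at this averages no change without dE2F1/dDP (3.77 to 3.75) and a fall with it (7.86 to 3.68). Its low levels lie at or below the arrays' lower quartiles, so the size is inexact.

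The mean dE2F1/dDP effect was led by Dp (log2 2.94), w (1.87), CG14545 (1.87), the histone methyltransferase gene pr-set7 (1.34), CG41284 (1.28) and CG10630 (1.19), and on the low side by CG13840 (-2.92), Pig1 (-2.81), CG12310 (-2.72), CG11300 (-2.69), CG14265 (-2.68) and CG18649 (-2.65), from the authors' deposited table. Of the low side, only CG13840 was called lower with dE2F1/dDP alone in that table. Pig1, CG12310, CG11300 and CG14265 were called higher with miR-11 alone. Their differences when dE2F1/dDP was added to miR-11 were log2 -4.03, -4.47, -4.05 and -4.27, so part of their averages is the absence of that rise. For the lists, the spread of the arrays again ran with the comparison. The first component averaged -20.1 and -16.1 in the groups with dE2F1/dDP and 12.9 and 23.3 in the others. Replication genes had 40 of 48 positive (median log2 0.40, adjusted p = 1.35e-10; Mcm10 at 1.15), G2 and mitosis genes 46 of 52 (0.33, adjusted p = 1.64e-07; SMC2 at 0.82) and eye progenitor genes 24 of 24 (0.40, adjusted p = 5.04e-07; dpp at 0.74, all genes from the authors' deposited table). E2F pathway (0.50, adjusted p = 1.55e-09, and 4.7e-05 without E2f and Dp), photoreceptor (0.38, adjusted p = 2.59e-06), repair (0.34, adjusted p = 6.66e-05), growth (0.34, adjusted p = 0.000103), antennal (0.37, adjusted p = 0.000666), JNK (0.32, adjusted p = 0.000627), ecdysone (0.28, adjusted p = 0.00193), glia (0.30, adjusted p = 0.00377) and muscle lists (0.27, adjusted p = 0.000843) were higher. Their members with the largest values in the authors' deposited table were Dp, pnt (1.20, also for glia), tos (0.99), CycE (1.07), ss (0.88), puc (0.73), ImpL2 (0.85) and Prm (0.80). The germline list passed (adjusted p = 0.0441; spn-E at 0.91 in the authors' deposited table) and lost that with the correlation preset at 0.05 (adjusted p = 0.12). Salivary (median -0.58, adjusted p = 1.53e-14; ng3 at -2.27) and fat body genes (-0.52, adjusted p = 2.98e-08; Obp99b 2.83-fold lower, both from the authors' deposited table) were lower. The salivary value averages unlike changes. Without miR-11 that list had passed as higher on its mean (0.24, median -0.05), and with miR-11 present its median was -1.02. Muscle, glia and germline lists had not passed with dE2F1/dDP alone (adjusted p = 0.683, 0.408 and 0.171).

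Cell death and E(spl) complex and Bearded genes did not pass for the mean dE2F1/dDP effect (adjusted p = 0.506 and 0.605, the latter with a median of -0.04 and a mean of 0.06), and CG17836 (0.89) and gro (0.77) were their largest values in the authors' deposited table. W stood at 0.15, rpr at 0.14, grim at 0.04, skl at -0.11 and E2f at 0.31 in the authors' deposited table. limma called 14 probe sets higher and 13 lower, among them 1637554_a_at (log2 change 2.94, SE 0.44, adjusted p = 0.0374) and 1638279_at (-2.91, SE 0.26, adjusted p = 0.00222). The first of these was not past the threshold with a block for the replicate number or without most single arrays. The total of 27 was 58 without miR-11 replicate 1 and 11 without replicate 3 of the genotype with all 3 transgenes.

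The interaction asks whether the change with all 3 transgenes departs from the sum of the separate changes. Gyc-89Da (log2 3.70), CG2177 (3.32), Rala (2.97), Cyp4g1 (2.43), CG7203 (2.13) and jhamt (2.06) lay above that sum, and Sgs4 (-5.16), Sgs3 (-4.72), Sgs8 (-4.42), Sgs5 (-4.32), Cyp6a17 (-4.16) and Eig71Ee (-4.14) below it, in the authors' deposited table. Gyc-89Da, CG2177, Cyp4g1 and jhamt were called lower in all 3 transgenic genotypes, so their sum counts that fall repeatedly, and a sum of falls that large can lie below what the arrays can measure. Their places at the top are therefore no evidence of an interplay of the transgenes. The salivary list lay below additivity (median log2 -0.93, adjusted p = 9.32e-106, and 0.000359 on ranks), as did the fat body list (-0.29, adjusted p = 8.93e-07, but 0.087 on ranks; Lsp1gamma at -2.65 from the authors' deposited table). The muscle (0.42, adjusted p = 1.41e-07; Unc-89 at 1.69) and glia lists (0.33, adjusted p = 0.000445; Mdr65 at 1.38) lay above it, as did replication genes (0.17, adjusted p = 0.0386; RnrL at 0.65, all genes from the authors' deposited table), a call lost with the correlation preset at 0.05 (adjusted p = 0.379). G2 and mitosis (ncd at 0.64), cell death (median 0.01, mean -0.06; egr at -0.80) and E(spl) complex and Bearded genes (median 0.10; dpn at 0.54, all from the authors' deposited table) did not pass. W lay at -0.35, rpr at 0.14, grim at 0.18, skl at 0.43, E2f at -0.05, Dp at 0.17 and w at -0.96 in the authors' deposited table. limma called 6 probe sets above additivity and 3 below it (adjusted p under 0.05), and the total of 9 was 16 without miR-11 replicate 1. For 3 of the 9 the sum of the separate changes lies below the lower quartile of every array, where a floor of the measure would give an interaction by itself.

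Changes by each transgene were last set side by side in comparisons that share no arrays. The dE2F1/dDP changes without and with miR-11 correlated across probe sets (Pearson r = 0.57, Spearman rho = 0.58), and r was 0.59 across the 13281 genes of the authors' deposited table. The miR-11 changes without and with dE2F1/dDP hardly did (r = 0.10, rho = 0.05 across probe sets; r = 0.08 across genes of the authors' deposited table). Genes are not independent replicates, and the groups with dE2F1/dDP also had the lower mean scores on the first component (-20.1 and -16.1, against 12.9 and 23.3), so that spread runs with this correlation. Single arrays carried much of the dE2F1/dDP value, which was 0.23 without control replicate 1 and 0.17 without miR-11 replicate 3. Of the 29 probe sets called with miR-11 alone, 25 had the same direction when dE2F1/dDP was present and 6 were called there as well. Of the 12 called with dE2F1/dDP alone, 7 had the same direction when miR-11 was present and 2 were called there as well. Of the 10 called with miR-11 present, 6 had the same direction without it. However, both the 12 and the 29 include the 7 probe sets called the same way in all 3 transgenic genotypes. Most of these had little further change when the other transgene was added. For example, 1626088_at stood at 4.32 with miR-11 and 4.30 with all 3 transgenes. The counts of direction therefore cannot be set against the correlations.

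**Figure D3:**
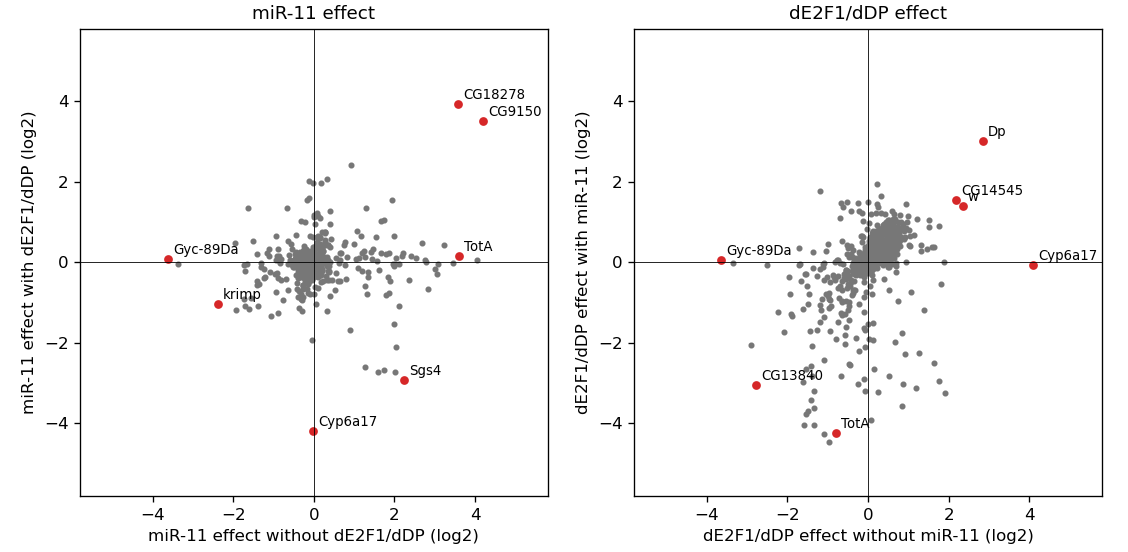
Left, the miR-11 effect with dE2F1/dDP (vertical axis, log2) against that without it (horizontal axis, log2), and right, the dE2F1/dDP effect with miR-11 against that without it, from the authors' deposited table, 1 grey point for each gene that was called, named or on a list. CG9150 and CG18278 lie above 3 on both axes of the left panel, whereas TotA is at 3.60 and 0.16, and Dp is at 2.85 and 3.02 in the right panel.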

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

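The tests on array signal, shared changes, single arrays and salivary genes in this part were chosen after their result was seen, while the interaction test, the gene lists and the counts of other splits were set before, and the list test was adapted after seeing the files. The change with miR-11 differed according to the presence of dE2F1/dDP for 9 probe sets (limma interaction, adjusted p under 0.05). For 3 of them, 1624543_s_at (log2 4.29) included, the sum of the separate changes lies below the lower quartile of every array, where a floor of the measure would give an interaction by itself, which was not tested. Probe set 1629242_x_at (4.23) was low with miR-11 alone. Probe set 1628052_at (-4.16) was high with dE2F1/dDP alone, and 1631349_s_at (-2.65) stood higher in both genotypes with separate transgenes (5.41 ± 0.46 and 4.68 ± 0.24, SD, n = 3) than in the control (3.66 ± 0.20). The low levels of these 2 probe sets lie near or below the arrays' lower quartiles (3.75 to 3.97), so the sizes of their interactions are inexact. Of 100 drawn splits of the 12 arrays, 2 gave as many as 9, the real one included. The highest other split called 5094, which points to a structure of the samples apart from genotype. At gene list level the interaction test over genes of the authors' deposited table passed for salivary gland (median log2 -0.93), fat body (-0.29), glia (0.33), muscle (0.42) and DNA replication and S phase genes (0.17), the last of which lost its call with the correlation preset at 0.05 (adjusted p = 0.379).

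The arrays spread along a component that genotype does not account for as a whole. Arrays of miR-11 alone ran from -34.0 to 83.3, and the permutation p between genotypes was 0.54, so genotype is not the whole cause of this spread, though a share of it stays open. RNA degradation would raise the difference between 3' and 5' probe sets with the component for all 3 control transcripts, and for GAPDH the correlation was -0.81, although for eIF-4a it was 0.61. The amount of labelled target per array remains open: the spike-in signal, whose share of the mixture rises when sample RNA is low, correlated at 0.77 and at 0.53 without the 2 extreme arrays, which is too weak to settle it. With the spike-in signal as a covariate, an alternative chosen after seeing the data, the mean dE2F1/dDP effect had 41 probe sets called in place of 27.

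A small set of genes was changed in all 3 transgenic genotypes, with 8 genes called lower in the authors' deposited table (CG2177, CG31436, CG6129, Cyp4g1, GstD9, Gyc-89Da, Obp44a and jhamt) and 1 higher (CG15678, now pirk), named after their values were seen. On the arrays 7 probe sets were called the same way in all 3 comparisons, against a mean of 0.59 in 100 draws with no effect and lists of the same lengths, of which 0 reached 7. The 5 falls lay just above the highest draw (4) and the 2 rises within the range (highest 3), so chance shared through the control arrays may account for part of the set and stays open. A response graded with each transgene stays open too, as the probe sets differed. The 3 log2 changes lay a median of 0.29 apart, 1.39 apart in 1624393_at, a rise, and from 0.05 to 0.54 apart in the other probe sets. Of the 5 falls, 1628585_at ended at 4.03 to 4.10, near the arrays' lower quartiles (3.75 to 3.97), where a floor of the measure could level its changes. The other falls ended higher, from 4.30 upward. A difference in genetic background between the control stock and the transgenic stocks is a candidate explanation that the design confounds with the transgenes, and it stays untested, as does a biological response common to all 3.

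Genes of neighbouring tissues changed with genotype in both directions. All 6 salivary glue genes were higher with miR-11 alone (median log2 1.67), and their median with dE2F1/dDP alone was 1.30, so the rise was not particular to miR-11. The miR-11 median lay below the 2.11 of the other genes called higher, so carried-over salivary gland may account for part of those rises and the test does not settle the rest. The test was first computed over the whole salivary list (median 0.25) and then over the glue genes, as it was worded, and was undecided both ways. For genes higher in both miR-11 genotypes, such as CG9150, it is argued against, since the glue genes were at -1.27 with all 3 transgenes. Of the probe sets at least 1.5 log2 units higher with miR-11, 55 in number, 16.4% lost most of the difference without their highest array, which argues against a single array as the cause of the whole rise, although 30 were highest in miR-11 replicate 3 and only 13 were called. For the genes higher with miR-11 alone, tissue carry-over and a biological change both stay open, as array values of named genes were not used here.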

How the results depend on the processing

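Counts of called probe sets moved with the processing. Over 31 pairs of a named probe set and a comparison under 14 alternatives each, 383 of 434 values stayed past the threshold, 51 did not and 0 changed sign. The last count was largely fixed in advance. Named probe sets were the largest called changes, without overlap of the arrays where genotypes were compared directly, and most alternatives left out a single array. The kept signs are thus no evidence of stability. Gene-by-gene array weights, the spike-in covariate, the omission of 3 arrays, the correlation of 0.05, the test on ranks and the E2F list without E2f and Dp were chosen after seeing the data. In the following, counts are in the order miR-11, dE2F1/dDP and both against the control, both against dE2F1/dDP, both against miR-11, mean miR-11, mean dE2F1/dDP and interaction, with 29, 12, 17, 7, 10, 22, 27 and 9 as reported. Array weights by the default method gave 3163, 3271, 147, 1165, 8869, 2965, 8318 and 1747, but that estimate did not converge and put a weight of 165 on miR-11 replicate 2. Gene-by-gene weights gave 494, 1533, 98, 402, 3957, 539, 6210 and 268. All reported calls were kept in both. Fits on only the groups compared, with fewer residual degrees of freedom, gave 10 for miR-11, 4 for dE2F1/dDP, 4 for both against dE2F1/dDP and 3 for both against miR-11. Quantile normalization gave 3 for both against miR-11, and the dim filter 5 for the interaction. Without miR-11 replicate 3, control replicate 1 and dE2F1/dDP replicate 3, which scored highest on the first component, dE2F1/dDP had 19, both against dE2F1/dDP 12 and the interaction 17. The spike-in covariate gave 41 for the mean dE2F1/dDP effect. The authors' deposited table called 60, 46 and 113 genes against the control. Except where stated, the cause was not tested.

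With the replicate number as a block, dE2F1/dDP had 7 and both against miR-11 had 3, and no other count moved by over 1.5 times. Only 6 of 18 same-number pairs correlated above 0.1 and 5 of 12 arrays correlated best with their own number, so these correlations gave no evidence of pairing. Other measures followed the number. The 3' minus 5' difference of eIF-4a was 1.68 to 2.07 in the replicate 3 arrays and at most 1.57 in all others, while that of GAPDH was not ordered this way. On the second component every replicate 1 array scored positive, and replicates 2 and 3 did so only with miR-11. A batch by replicate number, which the main fit does not model, stays possible. Leaving out each array in turn gave 14 to 45, 5 to 19, 9 to 18, 4 to 7, 3 to 48, 18 to 31, 11 to 58 and 7 to 16 in the order above. The reported calls did not change sign, which their selection for strong change made likely. The correlation of the miR-11 changes ranged from -0.0405 (without dE2F1/dDP replicate 2) to 0.199, with -0.0214 without miR-11 replicate 3, and that of the dE2F1/dDP changes from 0.17 to 0.65. With the correlation preset at 0.05, 2 lists in place of 8 passed with miR-11 and 9 in place of 16 with all 3 transgenes. On ranks, calls were lost for the hemocyte list with miR-11 (adjusted p = 0.0969) and for the mean miR-11 effect (0.0834), for the cone and pigment list with dE2F1/dDP (0.0772), and for the ecdysone (0.216), glia (0.182), stress (0.355) and hemocyte lists (0.05) with all 3 transgenes. So was the stress list for both against dE2F1/dDP (0.313), besides the fat body and salivary values given above. Gained on ranks were E2F pathway (0.0207) and muscle (0.0297) with miR-11, stress for both against miR-11 (0.0391), repair (0.0138) and E2F pathway (0.0408) for the mean miR-11 effect and G2 and mitosis for the interaction (0.00728).

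Not run for want of gene names on the arrays were a summary per gene, and for the gene lists, transgenes and named genes an estimated correlation, the replicate block, quantile normalization, the dim filter and single arrays left out. The seed site alternatives were not run either. Unadjusted p under 0.05 was reached by 477, 701, 550, 303, 546, 449, 1089 and 312 probe sets, where chance alone would give 938.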

Other observations

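The counts of other splits and the ring gland test were set before their result was seen, and the neighbour test after some gene positions were known. Several endocrine genes were lower with all 3 transgenes, a group that was noticed in the data, is on no list written beforehand and was not tested as a list. The steroid hormone synthesis genes phm (log2 -1.66), spok (-1.44) and sad (-1.07), which are active in the ring gland, were called lower in the authors' deposited table, together with Akh (-2.08), the juvenile hormone synthesis gene jhamt (-1.18) and the insulin-like peptide gene Ilp5 (-1.46). Ilp2 (-1.02, pfp = 0.0903) and Ilp3 (-0.38, pfp = 0.66) were not called in the authors' deposited table. Other members were as low with the separate transgenes in the authors' deposited table, jhamt at -1.52 with miR-11 and -1.72 with dE2F1/dDP and Ilp5 at -1.51 with dE2F1/dDP. In the same genotype, 3 further steroid synthesis genes stood at -1.21 for nvd, -0.69 for CG12068, now sro, and -0.15 for dib in the authors' deposited table. Ring gland carried into the control samples may explain this, but the median of these 3 was -0.69 and dib hardly differed, so the question stays open.

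Some genes set the miR-11 genotypes apart from dE2F1/dDP alone. In the authors' deposited table CG18278, CG2065, CG9150, Cyp6a13 and nimC1 were called higher in both miR-11 genotypes and not with dE2F1/dDP alone, and 9 genes including krimp, Hsp70Ba and Rbm13 were called lower. A candidate explanation is linked segments of the miR-11 stock's genome. Of the 14 genes with a place in the gene order, 0 lay within 10 genes of another of the set, against a median of 0 in 10000 random draws, so 14 genes are too few to decide. A response to miR-11 itself is not excluded, and whether these messages carry pairing sites was not analysed here.

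Of the lists that no comparison with the control passed, ribosomal protein genes had medians of -0.02, -0.04 and -0.05 with miR-11, dE2F1/dDP and both, innate immunity genes 0.02, -0.003 and 0.002, brain neuron and neuroblast genes -0.06, -0.02 and 0.02, and the sex-composition list -0.15, 0.32 and 0.11 in the authors' deposited table. Germline genes had -0.01, 0.07 and 0.11. Medians near 0 did not mean that no member moved. In the same order, the innate immunity list had 1 member called higher and 1 lower, 1 and 1, and 1 and 3 in the authors' deposited table. Adjusted over the list alone, these counts were 2 and 4, 2 and 4, and 1 and 5. The germline list had 1 member called lower with miR-11 and 1 with both.

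With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split was the only 1 to reach its count in each case: 29 with miR-11 (highest other 1), 12 with dE2F1/dDP (highest other 0), 17 with both (highest other 0), 7 for both against dE2F1/dDP (highest other 0) and 10 for both against miR-11 (highest other 0). For the mean miR-11 effect 1 of 100 drawn splits, the real one, reached 22 (highest other 7). A chance count that high is thus unlikely, but 1 of 100 is the smallest share these draws can give. The 22 include 1626088_at and 1628585_at, which were called lower in all 3 transgenic genotypes. For the mean dE2F1/dDP effect 2 of 100 reached 27, and the other called 5372, which points to a structure of the samples. In single arrays, 14 probe sets of miR-11 replicate 2, 12 of miR-11 replicate 3 and 9 of control replicate 1 lay more than 1.5 log2 units above all other arrays, against at most 1 in each of the remaining arrays. Below all other arrays by that much lay 16 probe sets of miR-11 replicate 3, 4 of replicate 2 with all 3 transgenes and 1 of its replicate 1.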
